A study of Danio rerio with 12 samples.

How the data were processed

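The series holds RNA-seq of 12 zebrafish melanomas, 6 with MiniCoopR-GFP and 6 with MiniCoopR-MyrRSK, grouped by the sample titles. Total RNA was extracted with a column kit and polyA RNA was sequenced, per the labels' protocols. One table for the whole series was analysed. Its raw columns are whole-number read counts per Ensembl gene and library as deposited by the authors, and they are not normalized. A second column per library, also made by the authors, is a signal: the raw count divided by 1 size factor per library, since the ratio of the columns is the same for every gene of a library (largest relative spread 9.84e-10). The deposited log2 fold changes, their standard errors and the p-values are the authors' own statistics. STAR 2.6.1d, HTSeq 0.6.0, DESeq2 and the genome build Zv9 are named per the submitters' processing notes, without their order or settings. The DESeq2 version, the annotation release and whether counting used strand are not given in the sources used here. Every gene in the table has a mean normalized count of at least 5.08, so genes below that are not analysed here, nor are genes of the mitochondrial genome or crestin.

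The table has 27827 genes with symbols and coordinates. Symbols were taken from it and, for list matching, also from a table of current names that held 68.5% of the IDs; 570 genes had no symbol in the file. Library totals ran from 61750434 to 72257237 counts, so counting error is small for all but low genes and the spread between tumours sets the precision. No pair of libraries was the same library: the smallest of 66 pairwise chi-square values per degree of freedom was 183. Spearman correlations of the counts ran from 0.884 to 0.939 within GFP and from 0.932 to 0.961 within MyrRSK melanomas. On the first principal component of log2 CPM (18.2% of the variance) GFP 1 and GFP 2 stood apart from the other libraries, and the second (16.4%) separated the groups.

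Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, robust quasi-likelihood fit, group as the only term). The filter left 26866 genes, and genes with a Benjamini-Hochberg adjusted p under 0.05 are called. Standard errors of log2 fold changes were derived from the fold change and the F statistic. CPM values use the TMM-scaled library sizes, and log2 CPM has a prior count of 1. For gene lists, the mean log2 CPM per library was compared by an exact two-sided permutation test over all 924 assignments of the libraries, whose smallest p is 0.00216. Lists were also tested with limma 3.58.1 by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry, adjusted over the 46 lists with at least 4 tested members. The 47 lists, of pathways and of markers of other cell types, were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Then 6 list members were left out because their names showed them to be other genes.

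The rule for named genes takes calls whose symbol is not a clone or placeholder name and whose mean normalized count is at least 50: the 12 largest rises and the 12 largest falls. For each list described it takes up to 4 called members with the smallest adjusted p or, where none was called, up to 2 with the highest mean. The rps6ka family, mitfa, braf, sox10, crestin, ppargc1a and ppargc1b are always named where measured; another gene of this rule and a list related to it are not reported here. Genes outside the rule are said to be chosen after their values were seen.

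The procedure was tested on simulated counts for this comparison, with 200 changed genes and the real means, depths and dispersions (26362 genes after the filter). Of 100 genes changed 8-fold edgeR called 80, and of 100 changed 2-fold it called 7, with 3 unchanged genes called. DESeq2 1.42.0 on simulated counts of the same kind called 93 and 24, with 56 unchanged genes called. With no gene changed edgeR called 0 genes and camera 0 lists. Each gene was drawn independently in the simulation, so it does not test the list calls where genes of a list vary together. Alternatives were other scalings (DESeq2 median ratio, upper quartile), filters (none, mean of at least 100), pseudocounts of 0.5 and 5, tools (DESeq2, limma-voom with and without quality weights, edgeR without robust fitting), thresholds, list tests, the replicate number as a block, and each library left out in turn. Fits with libraries left out applied the filter anew, so a list could gain low-count members there. Figures were drawn with matplotlib 3.10.9.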

Results

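Gene expression was measured by sequencing polyA RNA from 12 zebrafish (Danio rerio) melanomas. In 6 of them the tumour carried the MiniCoopR vector with GFP (the GFP group), and in 6 it carried MiniCoopR with MyrRSK, a form of the ribosomal S6 kinase RSK (the MyrRSK group). MiniCoopR is a transgenesis vector that brings mitfa, the melanocyte master regulator, back into mitfa-deficient fish together with a gene of interest. The libraries held 61750434 to 72257237 gene counts each, and 27827 genes were listed. The labels do not state that each melanoma came from a different fish, so p-values measure the spread between these 12 samples. The series title names oxidative phosphorylation and melanoma invasion, and the design implies a single comparison, MyrRSK against GFP melanomas.

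MyrRSK melanomas differed from GFP melanomas in 109 of 26866 tested genes, of which 78 were higher and 31 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 6 per group). The call with the smallest p was COL9A1 (ENSDARG00000073699, chromosome 11, 11396866 to 11422659, Zv9), a collagen IX chain of cartilage and eye matrix. It rose from 2.14 ± 0.385 to 32.0 ± 10.5 CPM (counts scaled to a common library size; SD, n = 6), a log2 fold change of 3.91 ± 0.26 (SE) with an adjusted p of 2.45e-05. The fatty acid desaturase gene scdb rose by 3.42 ± 0.60 on the log2 scale, the voltage-gated potassium channel subunit gene KCNG2 by 4.05 ± 0.58, and camk2d2, a calcium/calmodulin-dependent kinase gene, by 3.30 ± 0.44. Among the falls, pfas (ENSDARG00000003750, chromosome 20), which encodes an enzyme of purine synthesis, went from 232 ± 141 to 28.7 ± 7.66 CPM (log2 fold change -3.01 ± 0.43, adjusted p = 0.0204). The TGF-beta receptor gene tgfbr1a (ENSDARG00000017494, chromosome 2) fell by 1.38 ± 0.22 on the log2 scale, from 15.3 ± 3.11 to 5.84 ± 1.28 CPM (adjusted p = 0.0241). For COL9A1, scdb and camk2d2 all 6 MyrRSK libraries lay above all 6 GFP libraries, for KCNG2 5 did, and for pfas and tgfbr1a all 6 lay below.

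The 12 largest rises by the naming rule also held the muscle genes pvalb2, myhc4 and myhz2 and the genes lgi2b, phyhiplb, IFITM10, EPB41L1 and kif1ab, a neuronal kinesin. Their log2 fold changes ran from 3.05 for kif1ab to 7.11 for pvalb2, with adjusted p from 0.0204 for IFITM10 to 0.0485 for pvalb2. The 12 largest falls were completed by nrxn3a (-3.30), vwa2 (-2.74), gas1b (-2.52), MPP7 (2 of 3) (-2.33), dtna (-2.28), CD200R1L (-2.13), acad11 (-1.73), CCNJL (-1.38), dfna5 (-1.37) and ypel1 (-1.37). Their adjusted p lay between 0.0241 for ypel1 and 0.0489 for nrxn3a. In 8 of these 10, which leaves out nrxn3a and CD200R1L, all 6 MyrRSK libraries lay below all GFP libraries. Of the 109 genes, 103 were also past an adjusted p of 0.05 in the authors' deposited table, all 109 had the same sign there, and the other 6 had no p in it. These 6 include the 3 largest rises named, pvalb2, myhc4 and myhz2, and the largest fall, nrxn3a. Their deposited log2 fold changes were 1.15, 2.07, 2.44 and -2.09. Deposited values were smaller in size for other named calls too, such as COL9A1 (3.55 against 3.91) and KCNG2 (2.79 against 4.05). The settings behind them are not given, so the deposited estimates may be on another scale than those of edgeR. The authors' deposited table itself lists 678 higher and 539 lower genes at that threshold. The number of calls rested on single libraries: without GFP 1, GFP 2 or GFP 5 it was 50, 1 and 37 genes higher, and without MyrRSK 1, 2, 4, 5 or 6 it was 23, 44, 2, 24 and 24. Genes lower numbered 0, 55, 14 and 84 without GFP 2, 4, 5 or 6 and 4, 10, 12, 0, 4 and 5 without MyrRSK 1 to 6. Where edgeR called 0, without GFP 2 or MyrRSK 4, 2030 and 1824 were lower at an unadjusted p under 0.05. With a score of skeletal muscle markers as a covariate, 1 gene was higher and 0 lower with edgeR (1259 and 1125 unadjusted). COL9A1 kept its call in each of these fits. The calls of KCNG2, IFITM10, camk2d2, EPB41L1 and pfas ended without GFP 2 or MyrRSK 4, that of tgfbr1a also without MyrRSK 1, and that of scdb without GFP 1, 2 or 3 or MyrRSK 1, 4, 5 or 6. Of 30 called genes named in the text, the calls of 14, 29, 12, 9, 14 and 3 ended without GFP 1 to 6, and those of 21, 15, 10, 28, 21 and 19 without MyrRSK 1 to 6.

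**Figure D1:**
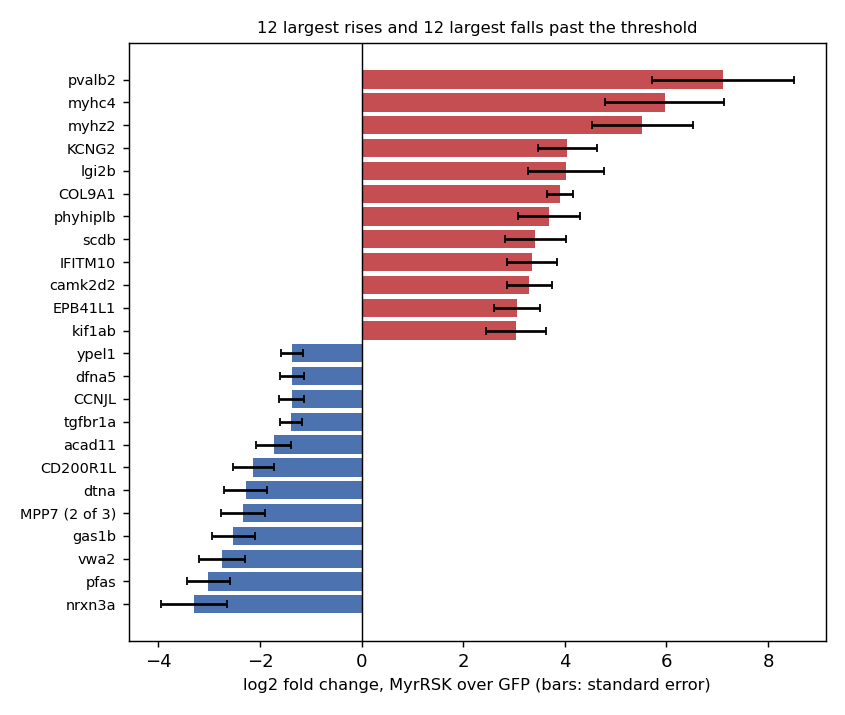
Log2 fold change of MyrRSK over GFP melanomas (x axis) for the 12 largest rises and 12 largest falls past the threshold with a gene symbol (y axis). Bars give the edgeR estimate and whiskers its standard error (n = 6 per group); rises run from 3.05 (kif1ab) to 7.11 (pvalb2) and falls from -1.37 (ypel1, dfna5) to -3.30 (nrxn3a).

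Genes of the mitochondrial respiratory chain were higher in MyrRSK melanomas as a group. The mean log2 CPM of the 95 nuclear-encoded subunits of complexes I to V rose from 5.43 ± 0.19 in GFP to 5.76 ± 0.10 in MyrRSK melanomas (SD, n = 6), a difference of 0.33 ± 0.09 (SE) or 26.0%. The exact two-sided permutation p was 0.00433 (0.0569 adjusted over the 46 lists tested), and 5 of 6 MyrRSK libraries lay above every GFP library. Of the 95 genes, 79 had a positive and 16 a negative log2 fold change. No single subunit gene passed the threshold over all genes tested with edgeR, 28 were higher and 0 lower at an unadjusted p under 0.05, and 7 were higher and 0 lower when adjusted over the list alone. DESeq2 called 11 of the 95 higher, limma-voom 0, and the authors' deposited table lists 10 higher and 0 lower. The genes cox5aa (0.72 ± 0.17, 112 ± 20.3 against 185 ± 23 CPM) and cox7a2 (0.76 ± 0.18) of complex IV, ndufb6 of complex I (0.68 ± 0.18) and the ATP synthase-associated USMG5 (0.65 ± 0.17) had the smallest p and were chosen after their values were seen. The pair of subunit genes with the highest mean, ATP5B (0.26 ± 0.26, adjusted p = 0.662) and atp5a1 (-0.11 ± 0.21, adjusted p = 0.832), did not pass. The camera test with a preset correlation gave an adjusted p of 7.90e-10 for the list, and adjusted p = 0.376 with an estimated correlation. The fry test, which does not compare the list with other genes, gave 0.0364. The skeletal muscle list described below was also higher in MyrRSK melanomas, by 1.67 ± 0.52, and with that score as a covariate the difference of the respiratory list was 0.25 ± 0.12 with an exact p of 0.0823.

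By complex, the mean difference was 0.38 ± 0.09 for the 42 genes of complex I (exact p = 0.00433), 0.31 ± 0.09 for the 19 of complex IV (exact p = 0.0108) and 0.28 ± 0.11 for the 20 of complex V (exact p = 0.0390). Without GFP 1, 2, 3 or 6 or MyrRSK 1, 2, 4 or 6 complex V did not pass (exact p from 0.0628 to 0.0693), and without both GFP 1 and 2 complex IV did not (exact p = 0.0571). With the muscle score as a covariate the differences were 0.26 ± 0.12 for complex I, 0.32 ± 0.14 for complex IV and 0.15 ± 0.16 for complex V, with exact p of 0.0779, 0.0498 and 0.366. Complex II (0.33 ± 0.15, exact p = 0.0541) and complex III (0.30 ± 0.17, exact p = 0.136) did not pass. Complex II did pass without GFP 4, GFP 6, MyrRSK 2 or MyrRSK 5 (exact p from 0.0325 to 0.0498). Complex III passed without GFP 5 (0.40, exact p = 0.0281), and its difference was 0.19 without GFP 6. Adjusted over each list alone, 7 genes of complex I, 4 of complex IV, 2 of complex V and 1 of complex III were higher and none was lower in any of these complexes. The complex IV genes include COX5A (2 of 3), whose annotated span on chromosome 25 overlaps that of the glycolysis gene pkmb, chosen after its values were seen. Their mean CPM were 153 and 154 in GFP and 228 and 231 in MyrRSK melanomas, so the same reads may enter both lists. In the 46 assembly factors of the chain (0.29 ± 0.11, exact p = 0.0303) the copper chaperone gene cox17 (ENSDARG00000069920, chromosome 9) passed over all genes tested. It rose from 21.4 ± 3.02 to 54.9 ± 8.21 CPM (log2 fold change 1.36 ± 0.17, adjusted p = 0.0165) and was higher in 6 of 6 MyrRSK libraries than in any GFP library. Its call ended without GFP 2. Adjusted over the list alone 5 assembly factors were higher and 0 lower. The list did not pass without GFP 1, 2 or 6 or MyrRSK 1, 4 or 5 (exact p from 0.0519 to 0.0628), nor with the muscle score as a covariate (0.20 ± 0.16, exact p = 0.221). The 80 mitochondrial ribosomal protein genes differed by 0.27 ± 0.14 (exact p = 0.0801), with 0 past the threshold with edgeR over all genes or over the list alone and 15 higher at an unadjusted p under 0.05. DESeq2 called 2 of them higher and limma-voom 0. Without GFP 4 the difference of the list was 0.36 (exact p = 0.0130), and without both GFP 1 and 2 it was 0.15 (exact p = 0.290). The preset camera test called complexes I, III, IV and V, the assembly factors and the mitochondrial ribosome. With an estimated correlation none held: adjusted p = 0.376 with an estimated correlation for complex I, 0.483 for complexes III and V, 0.425 for complex IV, 0.473 for the assembly factors and 0.524 for the mitochondrial ribosome.

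**Figure D2:**
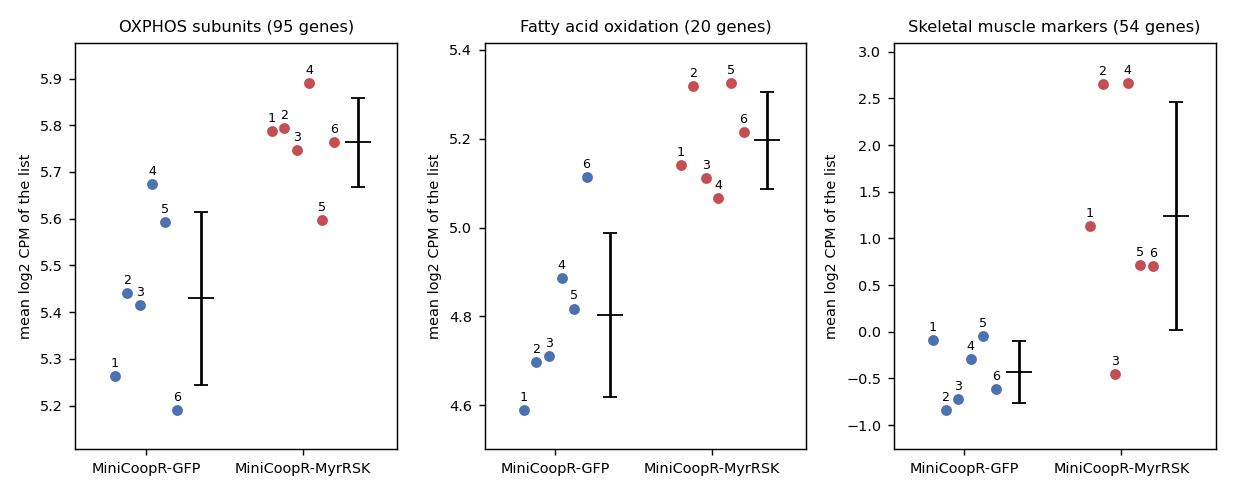
Mean log2 CPM of 3 gene lists (y axis) in each GFP and MyrRSK melanoma (x axis; points are libraries with their replicate number, the black bar is the mean with its SD, n = 6). The OXPHOS mean was 5.43 in GFP and 5.76 in MyrRSK melanomas, and in the muscle list MyrRSK 3 lay at the level of the GFP libraries.

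Mitochondrial fatty acid oxidation genes were higher by 0.39 ± 0.09 (exact p = 0.00649), with etfa (ENSDARG00000043944, chromosome 25), the gene of the alpha subunit of the electron transfer flavoprotein, past the threshold over all genes. The gene rose from 53.3 ± 7.68 to 121 ± 7.28 CPM (log2 fold change 1.18 ± 0.15, adjusted p = 0.0165). Its call ended without GFP 2 or MyrRSK 4. Adjusted over the list alone 4 of the 20 genes were higher and 0 lower, among them CPT1A (1 of 2), the mitochondrial carnitine acyltransferase (1.42 ± 0.36), and hadh (1.05 ± 0.28), both chosen after their values were seen. Antioxidant genes were higher by 0.39 ± 0.08 (exact p = 0.00216, the smallest these permutations can give) in 6 of 6 MyrRSK libraries. Glycolysis genes were higher by 0.35 ± 0.11 (exact p = 0.00866). Their highest scores were in MyrRSK 4 and MyrRSK 2, the libraries highest in muscle markers. The glycolysis difference was 0.25 and 0.19 without MyrRSK 2 or 4, and 0.27 without GFP 3, GFP 4 or MyrRSK 6, and passed in none of these (exact p from 0.0628 to 0.0844). The main fit tested 25 of 26 matched genes, and these fits filtered anew, so a low-count gene could enter the list. Over the 25 genes GFP 3 and GFP 4 scored 5.29 and 5.27, above the GFP mean of 5.17. MyrRSK 6 scored 5.52, like the MyrRSK mean. Leaving out any of them would thus not narrow that difference. Their 0.27 may come from a changed list and not from the library left out. With the muscle score as a covariate the glycolysis difference was 0.15 ± 0.14 (exact p = 0.290), against 0.39 ± 0.13 for fatty acid oxidation (exact p = 0.0260) and 0.35 ± 0.11 for antioxidant genes (exact p = 0.0238). In neither the antioxidant nor the glycolysis list did a gene pass with edgeR over all genes or over the list alone. At an unadjusted p under 0.05, 6 of 26 antioxidant and 7 of 25 glycolysis genes were higher and 0 lower. The glycolysis genes among them include pkmb, which may share reads with COX5A (2 of 3). DESeq2 called 2 higher in each, limma-voom 0, and the authors' deposited table lists 2 higher in each. Their members with the highest means were gstp1 (0.25 ± 0.50) and the thioredoxin gene zgc:56493 (0.56 ± 0.18), and eno1a (0.74 ± 0.23) and gapdhs (0.30 ± 0.24). All 3 lists were called by the preset camera test, which gave adjusted p = 0.372 with an estimated correlation for fatty acid oxidation and 0.376 for the others, and by fry (adjusted p = 0.0152, 0.0328 and 0.0364). Over all 46 lists the exact tests gave a smallest adjusted p of 0.0569, shared by these 3 lists, the respiratory list, complex I, muscle and hepatocyte markers. The tricarboxylic acid cycle (0.06 ± 0.11, exact p = 0.597), regulators of mitochondrial biogenesis (0.07 ± 0.06, exact p = 0.225) and cytosolic ribosomal proteins (-0.10 ± 0.24, exact p = 0.662) did not differ beyond their spread. The ribosomal difference was 0.0181 without GFP 5, and -0.24 and -0.22 without GFP 6 or MyrRSK 4. The coactivator genes ppargc1a (-0.21 ± 0.33) and ppargc1b (0.10 ± 0.24) did not pass.

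**Figure D3:**
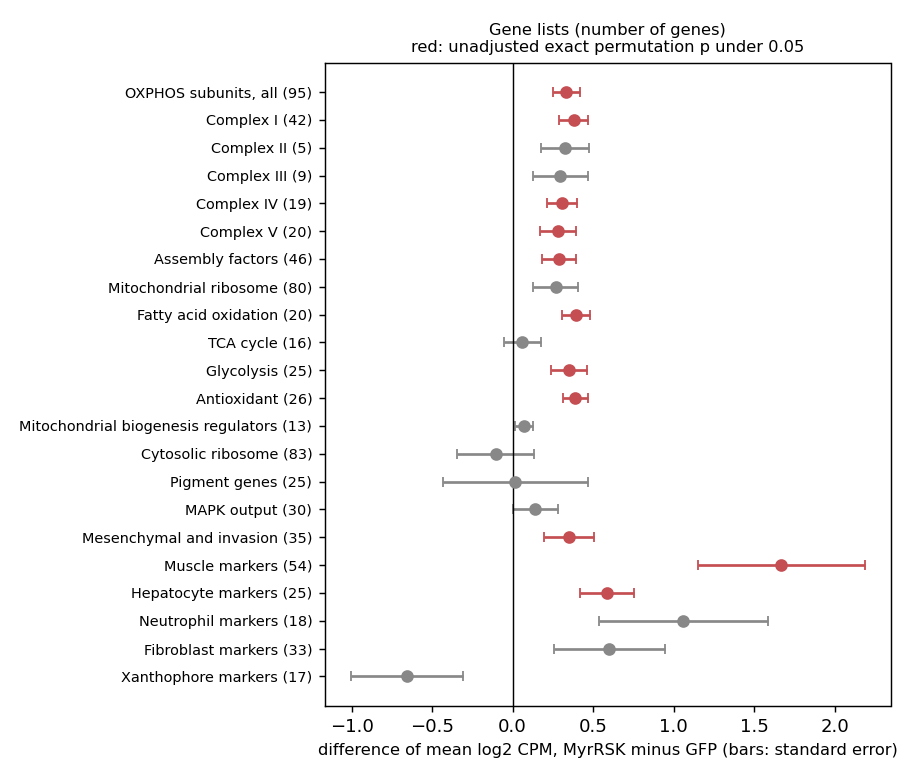
Difference of the mean log2 CPM between MyrRSK and GFP melanomas (x axis) for 22 gene lists (y axis, number of genes in brackets). Points are differences of group means, whiskers their standard errors (n = 6 per group), and red marks an unadjusted exact permutation p under 0.05; the respiratory list lies at 0.33 and muscle markers at 1.67.

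The zebrafish genes for RSK and its relatives did not rise in the tumours that carried MyrRSK. Of 8 measured members, 0 passed over all genes with edgeR, DESeq2 or limma-voom or over the list alone with edgeR, and 0 were higher and 3 lower at an unadjusted p under 0.05. Those 3 were rps6ka3b (-0.58 ± 0.24), rps6ka4 (-0.40 ± 0.17) and rps6kal (-0.62 ± 0.27). The values of the others were 0.42 ± 0.37 for rps6ka1, 0.37 ± 0.29 for RPS6KA2, -0.13 ± 0.21 for rps6ka3a, -0.44 ± 0.34 for RPS6KA5 and -0.19 ± 0.21 for RPS6KA6. Their mean difference was -0.15 ± 0.12 (exact p = 0.212), and -0.24 without GFP 4 (exact p = 0.0173). The labels give neither the species nor the paralog of the transgene, so these counts do not check its expression. The mitfa gene, which both vectors carry, stood at 297 ± 110 CPM in GFP and 257 ± 43.7 in MyrRSK melanomas (-0.21 ± 0.24, adjusted p = 0.718). The log2 fold changes of sox10 (-0.08 ± 0.30) and braf (-0.45 ± 0.19) did not pass either, with adjusted p of 0.917 and 0.292.

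Melanocyte pigment genes did not pass as a list (0.02 ± 0.45, exact p = 0.994; median log2 fold change of the members -0.25). Without GFP 6 their difference was -0.37 (exact p = 0.184), without GFP 5 it was 0.20, and with the muscle score as a covariate it was -0.53 ± 0.63 (exact p = 0.474). The premelanosome gene pmela had a log2 fold change of -1.34 ± 0.65 (adjusted p = 0.345), and tyrp1b differed by 0.25 ± 0.68. Output genes of the MAPK pathway, in which RSK acts downstream of ERK, did not pass as a list (0.14 ± 0.14, exact p = 0.348; median of the members -0.16). Without GFP 1 the difference was 0.26 (exact p = 0.00866), and without GFP 4 it was 0.0670. Of its 30 members 0 passed with edgeR (2 higher and 3 lower at an unadjusted p under 0.05), DESeq2 called 1 higher and 1 lower, and limma-voom called 0. The ERK phosphatase gene dusp6 had a log2 fold change of 0.95 ± 0.28 with an adjusted p of 0.128 with edgeR and 0.0329 with DESeq2, and 0.0356 in the authors' deposited table. The log2 fold change of dusp4 was -0.33 ± 0.28. Mesenchymal and invasion genes had a mean difference of 0.35 ± 0.16 (exact p = 0.0433, adjusted p = 0.153 over the 46 lists), with 0 members past the threshold with edgeR over all genes, 3 higher and 2 lower at an unadjusted p under 0.05, and 1 higher and 2 lower adjusted over the list alone. DESeq2 called 2 higher and 2 lower and limma-voom 0, and camera did not call this list (adjusted p = 0.174). Without GFP 2 to 6 or MyrRSK 2 to 5, each left out in turn, its exact p lay between 0.0606 and 0.0887. The main fit tested 35 of the 36 matched invasion genes, and these fits filtered anew, so the list itself may have changed. With the muscle score as a covariate the difference of the invasion list was 0.24 ± 0.23 (exact p = 0.335). Matrix metalloproteinase genes did not pass (0.22 ± 0.22, exact p = 0.348). Their difference was 0.38 without GFP 1 (exact p = 0.0325) and 0.11 without MyrRSK 2. DNA replication genes were called by the preset camera test (adjusted p = 0.00211; adjusted p = 0.609 with an estimated correlation), but their mean difference of 0.35 ± 0.28 did not exceed the spread (exact p = 0.253) and was 0.17 without GFP 1. Endoplasmic reticulum stress genes (0.33 ± 0.13, exact p = 0.0346) were called as higher by that test, with adjusted p = 0.483 with an estimated correlation. Their exact p was between 0.0584 and 0.0693 without GFP 4 to 6 or MyrRSK 1 to 5, each left out in turn. With the muscle score as a covariate their difference was 0.23 ± 0.20 (exact p = 0.273).

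Markers of skeletal muscle were higher in MyrRSK melanomas by 1.67 ± 0.52 on the log2 scale (exact p = 0.00866, adjusted p = 0.0569 over the lists), in 5 of 6 libraries above every GFP library. Over all genes tested 2 of the 54 markers passed, and adjusted over the list alone 26 rose, 0 fell and 28 did not pass. DESeq2 called 26 higher over all genes and limma-voom 0, with 27 higher at an unadjusted p under 0.05. The parvalbumin gene pvalb2 stood at 0.0863 ± 0.0947 CPM in GFP and 12 ± 15.7 in MyrRSK melanomas, the fast myosin heavy chain gene myhz2 at 0.436 ± 0.269 and 20.1 ± 24.1, and the tropomyosin gene tpma, chosen after its values were seen, at 0.232 ± 0.220 and 8.65 ± 11.3. MyrRSK 2 and MyrRSK 4 held most of these counts, with 21.6 and 39.8 CPM of pvalb2, 61.1 and 37.8 of myhz2 and 17.6 and 27.6 of tpma. The next highest MyrRSK library had 4.56, 8.34 and 2.51. Without both libraries the difference of the list was 0.94 (exact p = 0.0238). The annotated span of myhz2 (chromosome 5, 33843993 to 33887385, Zv9) includes that of myhc4 (33859370 to 33871477), so reads of these related genes could be split between them and their values are uncertain. With an estimated correlation the list's call was lost (adjusted p = 0.376 with an estimated correlation). Hepatocyte markers were higher by 0.59 ± 0.17 (exact p = 0.00866; adjusted p = 0.458 with an estimated correlation), with 3 of 25 higher when adjusted over the list alone and 0 past the threshold over all genes with edgeR (4 at an unadjusted p under 0.05; 4 higher and 1 lower with DESeq2, 1 higher with limma-voom). The gene tfa stood at 5.54 ± 7.65 and 78.2 ± 55.0 CPM, and rbp4 at 42.5 ± 26.7 and 75.4 ± 43.2. The hepatocyte difference was 0.51 ± 0.25 with the muscle score as a covariate and 0.39 without MyrRSK 2 and 4, and passed in neither (exact p = 0.0866 and 0.1). The main fit tested 25 of 27 matched hepatocyte genes, and the fit without these libraries filtered anew. Low-count genes could thus enter the list, and part of the fall to 0.39 may come from them.

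Neutrophil markers had a mean difference of 1.06 ± 0.52 that did not pass the exact test (p = 0.0758), with srgn at 1.54 ± 0.51 and mmp9 at 0.76 ± 0.90. It did pass without GFP 1 or GFP 2 (1.33 and 1.27, exact p = 0.0325 and 0.0476). The preset camera test called the list (adjusted p = 7.81e-05; adjusted p = 0.483 with an estimated correlation). The same test called fibroblast (0.60 ± 0.35), T and NK cell (0.69 ± 0.52) and macrophage markers (0.38 ± 0.33) as higher, with exact p of 0.110, 0.223 and 0.266 and with adjusted p = 0.498, 0.603 and 0.687 with an estimated correlation. Without GFP 1 the fibroblast difference was 0.83 (exact p = 0.0195). The T and NK cell difference was 0.42 and 0.41 without GFP 4 or MyrRSK 3, and that of macrophage markers 0.25 and 0.23 without GFP 5 or MyrRSK 3. Xanthophore markers were the 1 list called as lower (-0.66 ± 0.35, exact p = 0.0801; camera adjusted p = 0.0492, adjusted p = 0.498 with an estimated correlation). Adjusted over that list alone 4 of 17 genes fell, among them akr1b1 (-2.49 ± 0.53) and aox3 (-3.82 ± 0.99), both chosen after their values were seen. The markers with the highest means, gch2 (0.51 ± 0.83) and slc2a15b (0.17 ± 0.63), did not pass. DESeq2 called 4 xanthophore markers lower over all genes, limma-voom and edgeR 0 (6 lower at an unadjusted p under 0.05 with edgeR). The aox3 counts lay mostly in GFP 1 and GFP 2 (38.2 and 62.2 CPM), the libraries apart on the first principal component. The other GFP libraries had up to 6.60 CPM and the MyrRSK libraries up to 1.65. Without these 2 libraries the log2 fold change was -1.13 for aox3 and -2.20 for akr1b1. The difference of the list was then -0.26 (exact p = 0.352). It was -0.42 without GFP 2 and -0.81 and -0.82 without GFP 4 or 6 (exact p = 0.160, 0.0390 and 0.0325). In the iridophore list the purine synthesis gene gart fell by 1.18 ± 0.22 on the log2 scale (adjusted p = 0.0416), and in the endothelial list lyve1b rose by 1.96 ± 0.36 from a low level (0.174 ± 0.0727 to 0.686 ± 0.158 CPM). The call of gart ended without any 1 library except GFP 6, and that of lyve1b without any except GFP 3 or GFP 6. Neither list was called by camera (adjusted p = 0.0549 and 0.680).

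A stretch of chromosome 22 held a block of neighbouring genes that were higher in MyrRSK melanomas; it was singled out after its values were seen. Between positions 19493980 and 19837118 (Zv9, 343 kb) lie 24 tested genes with clone-derived names of the si:dkey-21e2 and si:dkey-78l4 series. All 24 had a log2 fold change between 1.97 and 4.01 and an unadjusted edgeR p under 0.05, and 8 passed the threshold over all genes. Their mean log2 CPM was higher by 3.23 (exact p = 0.00216, the smallest these permutations can give), with the 6 MyrRSK libraries between 2.29 and 4.27 and the 6 GFP libraries between -2.38 and 0.94. As the block was picked for its rise, this p describes the separation and is no independent test of it. Inside the same stretch lie 4 other tested genes, and all 4 had a positive log2 fold change (median 3.48). Their edgeR adjusted p ran from 0.0962 to 0.225. These genes were a 5S_rRNA gene, BX936298.2, ENSDARG00000093843 and ENSDARG00000093450. None of them was called, and whether they are related to the clone-named series or share its reads was not tested. They therefore do not show whether the rise reached beyond that series. The 20 tested genes next to the block, 10 on each side, had a median log2 fold change of 0.12, and 0 of them passed with edgeR (4 at an unadjusted p under 0.05). Reads of closely related neighbours can be shared between them, so the value of each single gene in the block is uncertain.

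**Figure D4:**
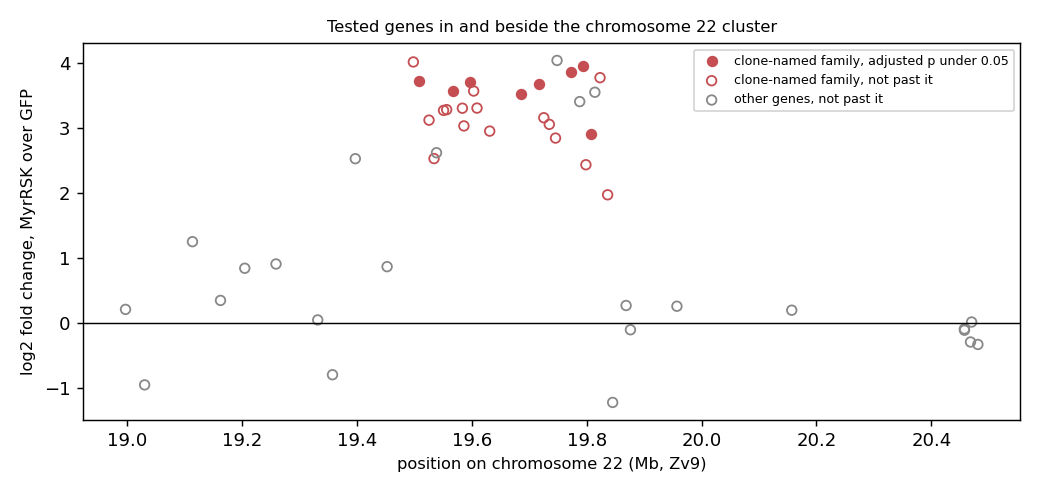
Log2 fold change of MyrRSK over GFP (y axis) by position on chromosome 22 in Mb of Zv9 (x axis) for tested genes in and beside the block. Red points are the 24 clone-named genes, filled where the adjusted p is under 0.05, and grey points are other genes. The red points lie between 1.97 and 4.01. The 4 grey points inside the block have a median of 3.48, and the median of the 20 flanking genes is 0.12.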

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

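The tests of the muscle covariate, of the shift of all genes and of the placement of calls were chosen after the results were seen; the rest were written down before their own result was seen. The count of genes past the threshold was not matched by other splits drawn. Of 100 splits of the 12 libraries, 1, the real one, called as many as 109 genes, and the highest other split called 21. The 100 were drawn from 462 distinct splits, so such a count was rare among mixed groups, but chance is not excluded. Nor do the splits tell which difference between the groups gave the calls. The count of lists called by camera with a preset correlation was not rare: 10 of the 100 splits, the real one among them, called at least the 20 lists of the real split, and the highest other split called 24. That split exchanged only GFP 6 and MyrRSK 6 and so kept most of the real grouping. An evenly mixed split, with GFP 1, 3 and 6 beside MyrRSK 2, 3 and 5, called 22. With DESeq2, 1 of 50 splits, the real one, reached 1573 genes, and another split called 1080, so with that tool mixed groups also gave many calls.

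The higher respiratory chain list was set against 3 technical explanations. RNA quality that favours short transcripts would move cytosolic ribosomal protein genes alike, yet the respiratory score minus the ribosomal score was higher in MyrRSK melanomas by 0.44 ± 0.19 (exact p = 0.0498); this holds weakly, as it did not pass without GFP 1, 3, 4 or 5 or MyrRSK 1, 2, 3 or 5 (exact p from 0.0563 to 0.0996), nor without both GFP 1 and 2 or both MyrRSK 2 and 4 (0.0857 and 0.0571). A shift of all genes by the scaling is argued against by the respiratory score minus the mean of all tested genes, in which a scale factor cancels: it was higher by 0.31 ± 0.12 (exact p = 0.0281), with 2 of 6 MyrRSK libraries above every GFP library, and did not pass without MyrRSK 4, both GFP 1 and 2, or both MyrRSK 2 and 4 (exact p = 0.0563, 0.0810 and 0.110). Muscle tissue in the samples stays open: adjusted for the muscle score the difference was 0.25 ± 0.12 against 0.33 ± 0.09 before (exact p = 0.0823 and 0.00433), and the call ended because the difference shrank and its error grew. The vector, which the design names, stays open as well; MyrRSK 3, with a muscle score in the range of the GFP libraries, had a respiratory score above all of them.

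The higher muscle markers may come from muscle tissue carried along with the tumour or from tumours that had grown into muscle, and the labels do not record the site or the margin of dissection. A lower share of tumour cells, with other cell types mixed in evenly, would raise markers of those types alike. Against such an even mix, the muscle score minus the mean of the 16 other cell type lists was higher in MyrRSK melanomas by 1.47 ± 0.58 (exact p = 0.0281). It did not pass without GFP 1, 2 or 6 or MyrRSK 1, 2 or 4 (exact p from 0.0519 to 0.0671), nor without both GFP 1 and 2 or both MyrRSK 2 and 4 (0.119 and 0.133). Muscle carried along would itself lower the share of tumour cells, so this test cannot tell an uneven mix from muscle alone. If muscle tissue were the source its genes should vary together within groups; their median pairwise correlation was 0.355 over all 54 markers, between the bounds set, while pvalb2, myhz2 and tpma shared their highest libraries (MyrRSK 2 and 4), so muscle tissue stays open. No test here bears on whether such muscle was dissected along or invaded. The levels were low, with mean CPM of 20.1 for myhz2 and 12 for pvalb2 in MyrRSK melanomas, mostly from MyrRSK 2 and MyrRSK 4.

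Among the 109 calls, 6 pairs of adjacent tested genes less than 100 kb apart moved in the same direction, 1 of them in the block on chromosome 22. Random draws of as many genes held at most 4 (10000 draws). Of the 4 pairs whose spans do not overlap, 2 of the 10000 draws held as many. The draws place each call independently, but the pairs include related neighbours, such as zgc:173962 and gstal with the same human ortholog. Related neighbours can share reads or move together. The draws thus argue only against independent placement of the calls as a whole, and not for the block by itself. More immune cells of the listed kinds are argued against as the whole source: adjusted for the mean of the macrophage, neutrophil, T and NK cell and B cell scores the difference of the block was still 2.83 ± 0.58 (exact p = 0.00433). Within groups the block score correlated with T and NK cell (0.66), macrophage (0.50), B cell (0.47) and neutrophil scores (0.17). A part from such cells thus stays open. Reads shared between near-identical neighbours stay open, with a median pairwise correlation of 0.626 between the genes of the block within groups and no genome sequence used here to compare them. A rarer cell type outside the lists or a haplotype shared by the fish of 1 group could also give such a block, and neither was tested.

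Single libraries far from the other 5 of their group were found in 18 of 228 groups of 6 (log2 CPM; the values in brackets are the gap to the next library over the range), where chance gives about 1 in 20. MyrRSK 3 was highest for srgn (0.787), for macrophage markers (0.632) and for B cell markers (0.714), and lowest for tyrp1b (0.637) and gch2 (0.663). MyrRSK 6 was lowest for KCNG2 (0.647) and highest for dfna5 (0.647) and eno1a (0.841). MyrRSK 2 was highest for nrxn3a (0.675) and lowest for interferon response genes (0.651), MyrRSK 4 was lowest for CPT1A (1 of 2) (0.683) and aox3 (0.696), and MyrRSK 5 was lowest for tfa (0.707). GFP 4 was highest for gapdhs (0.627) and lowest for rps6ka1 (0.678) and for the RSK family as a list (0.641). GFP 1 was highest for matrix metalloproteinases (0.733), and GFP 6 was lowest for slc2a15b (0.638).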

How the results depend on the processing

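Leaving out the libraries apart on the first principal component or highest in muscle markers, and the muscle covariate, for all gene lists as well, were chosen after seeing the data. The respiratory difference of 0.33 kept its direction in all alternatives and its exact p under 0.05 in all but the muscle covariate (0.25, exact p = 0.0823): it ran from 0.29 to 0.38 with 1 library left out, and was 0.30 both without GFP 1 and 2 and without MyrRSK 2 and 4. The counts of 78 higher and 31 lower genes moved most. They were 798 and 775 with DESeq2, where all 109 genes were again called, 338 and 240 at an adjusted p under 0.1, 1 and 0 with the muscle covariate (1259 and 1125 at an unadjusted p under 0.05), 23 and 7 without GFP 1 and 2, and 1 and 0 without MyrRSK 2 and 4 (1517 and 1525 unadjusted). With a mean of at least 100, which tests fewer genes, 77 were lower, and with limma-voom 20. With 1 library left out they ran from 1 to 104 higher and from 0 to 84 lower, lowest without GFP 2 and highest without GFP 6; without GFP 2, 1739 and 2030 genes still had an unadjusted p under 0.05. Each of those fits lacked 1 library, so group size alone does not account for the range. The cause of these moves was not tested. In the simulated counts DESeq2 called 56 unchanged genes and edgeR 3. The 20 lists called became 0 with an estimated correlation and 6 with fry, and ran from 17 to 24 with 1 library left out. With the replicate number as a block 6 genes were higher and 0 lower (1855 and 1310 unadjusted) and 18 lists were called; same-numbered libraries correlated between -0.15 and 0.10 and 0 of 12 correlated best with its own number, so the numbers do not pair the samples. Of the results for single named genes under the alternatives, 1266 kept direction and stayed called or not called, 323 lost the call, 22 gained one and 17 changed sign, none of the last among the called genes. In the main fit 30 of the named genes were called and 38 were not. The 1266 include results of the latter, which had no call to lose, so they do not give the share of calls that held. Signs changed with 1 library left out for sox10 (-0.23 to 0.0477), slc2a15b (-0.32 to 0.54), RPS6KA6 (-0.29 to 0.0110) and mmp9 (-0.0755 to 2.37). They also changed with quality weights for sox10 (0.0114), without GFP 1 and 2 for rps6ka3a (0.0776), mitfa (0.0123) and ppargc1a (0.0489), without MyrRSK 2 and 4 for slc2a15b (-0.25) and tyrp1b (-0.0579), and with the muscle covariate for slc2a15b (-1.44), tyrp1b (-1.18), gapdhs (-0.0558) and gch2 (-0.60).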

Other observations

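A cytokine gene and a receptor gene outside the naming rule, chosen after their values were seen, rose. The cytokine gene il13 went from 2.34 ± 1.66 CPM in GFP to 18.0 ± 9.51 in MyrRSK melanomas (log2 fold change 2.94 ± 0.56, adjusted p = 0.0431), and il13ra2, which encodes a receptor for that cytokine, from 7.74 ± 4.35 to 54.3 ± 21.1 CPM (2.81 ± 0.45, adjusted p = 0.0241). For both, 6 of 6 MyrRSK libraries lay above every GFP library. The call of il13 ended without any 1 library except GFP 6, and that of il13ra2 without GFP 2, MyrRSK 4 or MyrRSK 5.

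Besides the block on chromosome 22, runs of adjacent calls lay on chromosome 13 from 707116 to 728427 (Zv9), where zgc:173962, gstal and TMEM14A rose, and on chromosome 2 from 22861058 to 22931788, where 3 clone-named genes fell. The muscle myosin genes myhz2 and myhc4 on chromosome 5, whose spans overlap, made up another pair.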
